A study of Danio rerio with 6 samples.

How the data were processed

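RNA was measured by sequencing in 6 libraries from regenerating caudal fins of shha:GFP zebrafish (Danio rerio), a line in which green fluorescent protein marks cells that express the ligand gene shha. Per the labels, fish at 4 days after fin amputation received an injection into the body cavity of either buffer or BMS-833923 in that buffer. Fins were collected 5 hours later. BMS-833923 is a small-molecule inhibitor of Smoothened, the membrane protein that passes the Hedgehog signal into the cell, and its dose was 40 mg/kg. Tissue from the shha:GFP domains outward was kept, and each library was made from a pool of 4 fin regenerates. RNA was extracted with Trizol and libraries were made with a Kapa mRNA kit, per the labels' protocols. The groups are vehicle (3 libraries, replicates 2, 3 and 4) and BMS (3 libraries, replicates 2, 3 and 4). The treatment labels of BMS replicates 3 and 4 end in other digits than that of replicate 2, while the series' design text names BMS-833923 alone, so the 3 libraries were taken as 1 treatment. The labels name pools and not fish, so the p-values measure the spread between these pools.

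The authors deposited a table of whole-number counts of reads per gene row, and a smaller table of normalized values. Per the submitters' processing notes, the genome build was GRCz11 and the tools named are TopHat2 2.1.1, Bowtie2 2.33, HTSeq 0.6.1 and edgeR 4.3.2, with no role given for each. The gene annotation and the strand setting of the counting are not given in the sources used here. The count table has 31901 rows and 28531 distinct names, of which 541 stand on more than 1 row and 19 are gene names turned into spreadsheet dates. Rows were tested separately, and of rows that share a name the one with the highest mean count carries the plain symbol. The authors' normalized table is a signal on a CPM scale and has 11549 rows. Its values were checked against the deposited counts. Each value is a deposited count times 1 constant per library, with 100% of values whole within 0.001 of a read. Its columns sum to between 908876 and 1230418, so they are not plain CPM. It holds rows that pass 8 CPM in at least 2 libraries, which was checked for 11399 rows with unique names. Comparisons across all genes, the Hedgehog genes and the gene lists used the counts. The normalized table was used as an alternative.

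Total counts were 21491345, 22338924 and 22594355 in vehicle replicates 2, 3 and 4, and 16978747, 20278221 and 22659275 in BMS replicates 2, 3 and 4. A count of 0 in a library allows a level of up to 0.132 to 0.177 CPM of the total count, without TMM scaling (3 counts). This limit covers counting error only. Within each group, the counts of any 2 libraries differed by more than counting noise (chi-square per degree of freedom 32.9 to 131.9), so no library was taken for a second copy of another.

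The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr by group, robust=TRUE and group as the only term. It was two-sided, with Benjamini-Hochberg adjustment over the 18541 rows that passed the filter and a threshold of 0.05. CPM values given in the text are relative to the TMM-scaled library size. DESeq2 (1.42.0), limma-voom, the edgeR likelihood ratio test, other scalings and filters, a fold threshold of 1.2 and the omission of each library were alternatives. They were listed before the data were examined, as were 26 gene lists with 705 members, of which 677 were matched in the count table and 597 were tested. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists, with camera at an estimated correlation and fry beside it. Members were matched by symbol, with synonyms from the GRCz12tu RefSeq table, which was used for names only.

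Both groups carry the replicate numbers 2, 3 and 4, and a fit with that number as a block was listed beforehand as an alternative. Whether the numbers pair the libraries was checked from the correlation, across genes, of each library's deviation from its group mean. It was 0.58, 0.55 and 0.62 between vehicle and BMS libraries of the same number and between -0.50 and -0.16 for the other combinations. All 3 same-number values pass the limit of 0.1, so the numbers were taken to pair the libraries. The pairing comes from the data and not from a statement in the labels. Deviations from a group mean cancel out within the group, so the negative values follow largely from the positive ones and add no evidence. With 3 libraries per group there are few ways to match them, and a match without true pairs is not excluded. The fits with the block use a pairing read from these same libraries. Fits of DESeq2, the edgeR likelihood ratio test and limma-voom with the replicate block were added after seeing the data.

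The fits were tested on simulated data with the means, library sizes and pair differences of this comparison (18541 genes, 200 changed in each of 3 runs). Without the block the quasi-likelihood test found 0% of 2-fold and 20% of 4-fold changes. With the block it found 58% and 93%, with 7.7% of its calls false. DESeq2 with the block found 57% and 88%, with 7.4% false, and the likelihood ratio test with the block found 69% and 95.3%, with 15.4% false. The simulated genes varied independently of each other and changed alike in each pair. In the real data the quasi-likelihood test and DESeq2 with the block, alike in the simulation, called 0 and 72 genes. The simulated rates therefore do not carry over to those 72 genes.

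Genes named in the text follow a rule fixed before the data were examined. It takes the 4 Hedgehog direct targets, shha, smo, gli2a, gli2b, gli3 and each fibrillin gene. It adds, among genes at adjusted p under 0.05 with a mean of at least 1 CPM and no overlap between groups, the 15 largest falls and rises, and up to 4 members of each list at adjusted p under 0.05. Where fewer than 5 pass in a direction it takes the 5 of smallest p. Since the main test called no gene, the 5 of smallest p are given for it. The other 2 parts were then applied to the calls of DESeq2 with the block, with the same direction in all 3 pairs in place of no overlap. Of its 72 calls, 17 without a gene symbol or on a repeated row were left out. Other genes given as examples were chosen after their values were seen and are said to be so. Some genes that the rule takes are not reported here by name.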

Results

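The data are RNA counts from the distal part of caudal fin regenerates at 4 days after amputation, 5 hours after injection of buffer or of 40 mg/kg BMS-833923. Each group has 3 libraries, each made from 4 pooled regenerates. Total counts per library ran from 16978747 (BMS replicate 2) to 22659275 (BMS replicate 4). The design has 1 comparison, BMS against vehicle, and the series' design text gives its purpose as finding transcripts downstream of Sonic hedgehog in the regenerating fin. Vehicle and BMS libraries of the same replicate number deviated together, so the numbers 2, 3 and 4 are treated as pairs where a fit with the replicate block is given.

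The direct transcriptional targets of the Hedgehog pathway were lower after BMS-833923. The receptor gene ptch1 was at 30.0 ± 6.66 CPM in vehicle and 17 ± 7.39 CPM in BMS (mean ± SD, n = 3 libraries per group, as in the next values). The transcription factor gene gli1 was at 35.3 ± 6.96 and 18.9 ± 5.56 CPM, and hhip, which encodes a Hedgehog-binding antagonist, was at 12.6 ± 2.91 and 3.38 ± 1.22 CPM. Each of these genes was lower in BMS in 3 of 3 same-number pairs. The log2 fold changes in the edgeR quasi-likelihood fit were -0.82 ± 0.35 (SE) for ptch1, -0.90 ± 0.31 for gli1 and -1.88 ± 0.36 for hhip. Adjusted over the list alone, ptch1, gli1 and hhip passed 0.05 by edgeR (adjusted p = 0.0428 for ptch1, 0.0204 for gli1 and 0.0017 for hhip). Over all genes tested, the adjusted p of each by edgeR was 1. With the replicate block, DESeq2 called hhip (adjusted p = 0.000102) and gli1 (0.0232) over all genes, and ptch1 did not pass (0.0536). With the same block, edgeR's quasi-likelihood test called none of these genes (adjusted p over all genes 0.342 for hhip, 0.454 for gli1 and 0.477 for ptch1). Without vehicle replicate 2, without vehicle replicate 3 or without BMS replicate 4, hhip passed over the list alone and ptch1 and gli1 did not. Without BMS replicate 2, ptch1 did not pass either (0.0717 by edgeR, adjusted over the list).

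**Figure D1:**
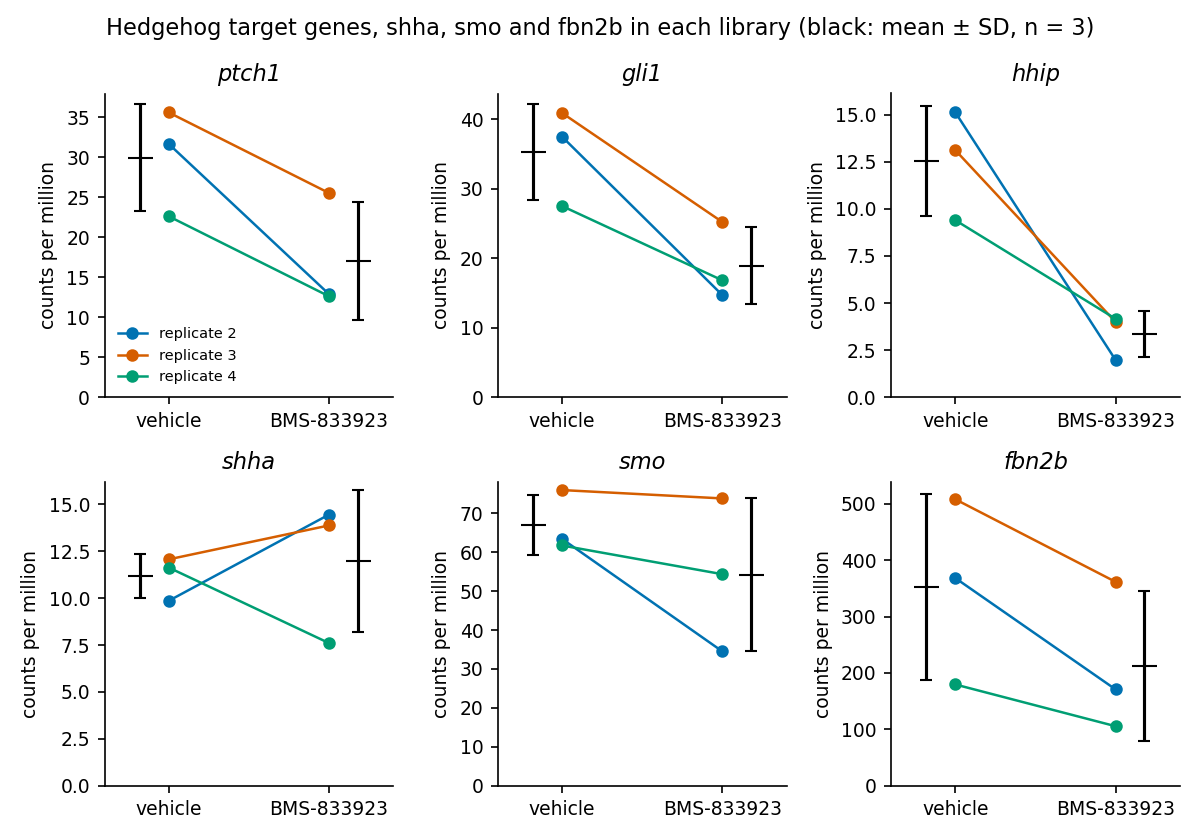
CPM (vertical axes, counts scaled to the TMM-scaled library size) of ptch1, gli1, hhip, shha, smo and fbn2b in the vehicle and BMS-833923 libraries. Points are libraries, coloured by replicate number and joined within a number, and black marks are the mean ± SD of 3 libraries. The lines of ptch1, gli1, hhip, smo and fbn2b fall in 3 of 3 pairs (smo by -0.04 log2 units in replicate 3), and that of shha in 1 of 3.

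The ligand and the other signalling genes of the pathway did not pass the test. The ligand gene shha was at 11.2 ± 1.17 CPM in vehicle and 12 ± 3.81 CPM in BMS, with a log2 fold change of 0.05 in the edgeR fit with the replicate block (95% interval -0.43 to 0.52). The Smoothened gene smo, which encodes the protein the compound inhibits, had a log2 fold change of -0.36 (interval -0.74 to 0.01) in the same fit. The Gli transcription factor genes gli2a, gli2b and gli3 had values of -0.18, -0.35 and -0.10. Their intervals reached up to 0.12, 0.05 and 0.24 and down to -0.49, -0.75 and -0.44. The sign of shha, gli2a and gli3 in the fit without the block depended on which library was left out. On the fixed list of 27 pathway components, 15 of 21 tested members had negative values, with a median log2 fold change of -0.18 (-0.31 to -0.04 with 1 library left out). Camera called this list lower at the preset correlation (adjusted p = 0.042), and the call was lost with an estimated correlation (adjusted p = 0.66). Genes known as Hedgehog-responsive in other tissues had a median of -0.04 over 17 members and were not called (camera adjusted p = 0.60).

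Of the fibrillins, which encode the backbone proteins of extracellular microfibrils, fbn2a and fbn2b were measured. The level of fbn2b was 352 ± 165 CPM in vehicle and 213 ± 133 CPM in BMS. It was lower in BMS in 3 of 3 pairs, by -1.11, -0.49 and -0.77 log2 units in replicates 2, 3 and 4. Without the block it did not pass (edgeR log2 fold change -0.73 ± 0.50, adjusted p = 1). DESeq2 with the replicate block gave -0.80 ± 0.20 and called it (adjusted p = 0.022), while edgeR's quasi-likelihood test with the block did not (adjusted p = 0.524). The level of fbn2a was 19.7 ± 3.51 and 15.7 ± 3.37 CPM, with a DESeq2 log2 fold change of -0.35 ± 0.23 (adjusted p = 0.885). Fibrillin 3, which the series title names, was not analysed here, because no symbol used here was matched to it. The fixed list of fibrillins and microfibril or elastic fibre genes was not called by camera (adjusted p = 0.23, median -0.05 over 24 members). Camera at the preset correlation called it lower without vehicle replicate 4 (adjusted p = 0.007) and without BMS replicate 2 (0.03), and without BMS replicate 4 its median was 0.14. With an estimated correlation and all libraries its adjusted p was 0.69. In the DESeq2 fit with the block, 2 of its members passed adjusted over the list alone and both were lower: fbn2b and the elastic fibre glycoprotein gene emilin1b (-0.68 ± 0.20).

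Across all genes, the edgeR quasi-likelihood test called 0 of 18541 genes. An unadjusted p under 0.05 was reached by 198 genes, where chance alone would give 927. Without the block, limma-voom called 0 genes, and DESeq2 and the edgeR likelihood ratio test called 1 gene each, hhip in both. Among the genes of smallest p that were lower in BMS, none of which passed, were hhip, slc4a8, col21a1 and lrrc74b, at log2 fold changes of -1.88, -2.02, -1.15 and -1.67. The genes of smallest p that were higher were a row named TCIM (1 of many), EML5, clec11a, sult1st4 and rgs11, at 2.02, 1.55, 1.49, 1.35 and 1.76. Some of these were low genes. Mean CPM in vehicle and BMS was 0.83 and 0.26 for lrrc74b, 0.40 and 1.19 for EML5, and 0.44 and 1.23 for clec11a. In the vehicle libraries rgs11 was at 0.13 to 0.28 CPM, near the level that a count of 0 allows. With the replicate block, edgeR's quasi-likelihood test and limma-voom again called 0 genes, with 1307 and 1319 genes at an unadjusted p under 0.05. DESeq2 with the block called 72 genes, 50 higher and 22 lower in BMS. The likelihood ratio test with the block called 110, 73 higher and 37 lower. Total-count scaling turned the split of the likelihood ratio calls to 27 higher and 49 lower. Of the 72 genes, 62 were also called by the likelihood ratio test with the block, 72 had an unadjusted p under 0.05 in the quasi-likelihood test with the block, and 72 moved the same way in 3 of 3 pairs. The 72 were selected from these same libraries by a fit with the block, so this overlap is no independent support. The blocked DESeq2 and likelihood ratio fits were chosen after seeing the data, and without both libraries of number 4 the DESeq2 count was 5 (hhip and mmp15b among them).

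Beside hhip, gli1 and fbn2b, the 22 genes called lower by DESeq2 with the block held sox9a, a transcription factor gene of cartilage and bone progenitors, which went from 26.5 ± 10.1 to 13.3 ± 6.87 CPM (log2 fold change -1.08 ± 0.24, adjusted p = 0.00607). The retinoic-acid-degrading enzyme gene cyp26c1 was at 32.6 ± 16.7 and 14.0 ± 10.5 CPM (-1.53 ± 0.29). Also called were col21a1 (a collagen, -1.16 ± 0.21), has2 (hyaluronan synthase, -0.95 ± 0.24), mmp15b (a membrane-bound metalloproteinase, -1.19 ± 0.30), tnc (tenascin C, -0.67 ± 0.18), crispld2 (-1.26 ± 0.28) and thsd7ba (-0.85 ± 0.23). The receptor tyrosine kinase feedback gene spry1 was at -1.05 ± 0.27 and the guidance ligand gene slit2 at -0.75 ± 0.20. The transcription factor gene mafa was at -1.12 ± 0.21, uhrf1, which maintains DNA methylation, at -0.91 ± 0.23, and the bicarbonate transporter gene slc4a8 at -2.04 ± 0.51. The largest fall was that of mucms1 (-2.85 ± 0.69), a low gene whose fold within pair 2 was -0.10.

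Of the 50 genes called higher by DESeq2 with the block, TCIM (1 of many) had the largest log2 fold change. It rose from 3.86 ± 1.92 to 15.7 ± 9.60 CPM (log2 fold change 2.01 ± 0.35, adjusted p = 3.5e-05). Its name marks it as 1 of several similar loci, so reads may be split among copies. The tyrosine-degrading enzyme gene tat was at 1.42 ± 0.63 and 6.13 ± 4.87 CPM (1.90 ± 0.49), with a fold of 0.07 log2 units within pair 3. The connexin gene cx30.3 (1.56 ± 0.31), the vesicle protein gene syt4 (1.47 ± 0.25), the sulfotransferase gene sult1st4 (1.33 ± 0.30) and the transcriptional corepressor gene nab1b (1.28 ± 0.35) were also called. The retinol-binding protein gene rbp4 (1.12 ± 0.29) and the prostaglandin D synthase gene ptgdsb.1 (1.17 ± 0.28) had folds of 0.05 and 0.15 within pair 3. The others named by the rule were ttc36, aste1a, arl5c, the serine protease gene tmprss13b, ccdc173 and myzap, at 1.23, 1.2, 1.17, 1.11, 1.07 and 1.07.

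**Figure D2:**
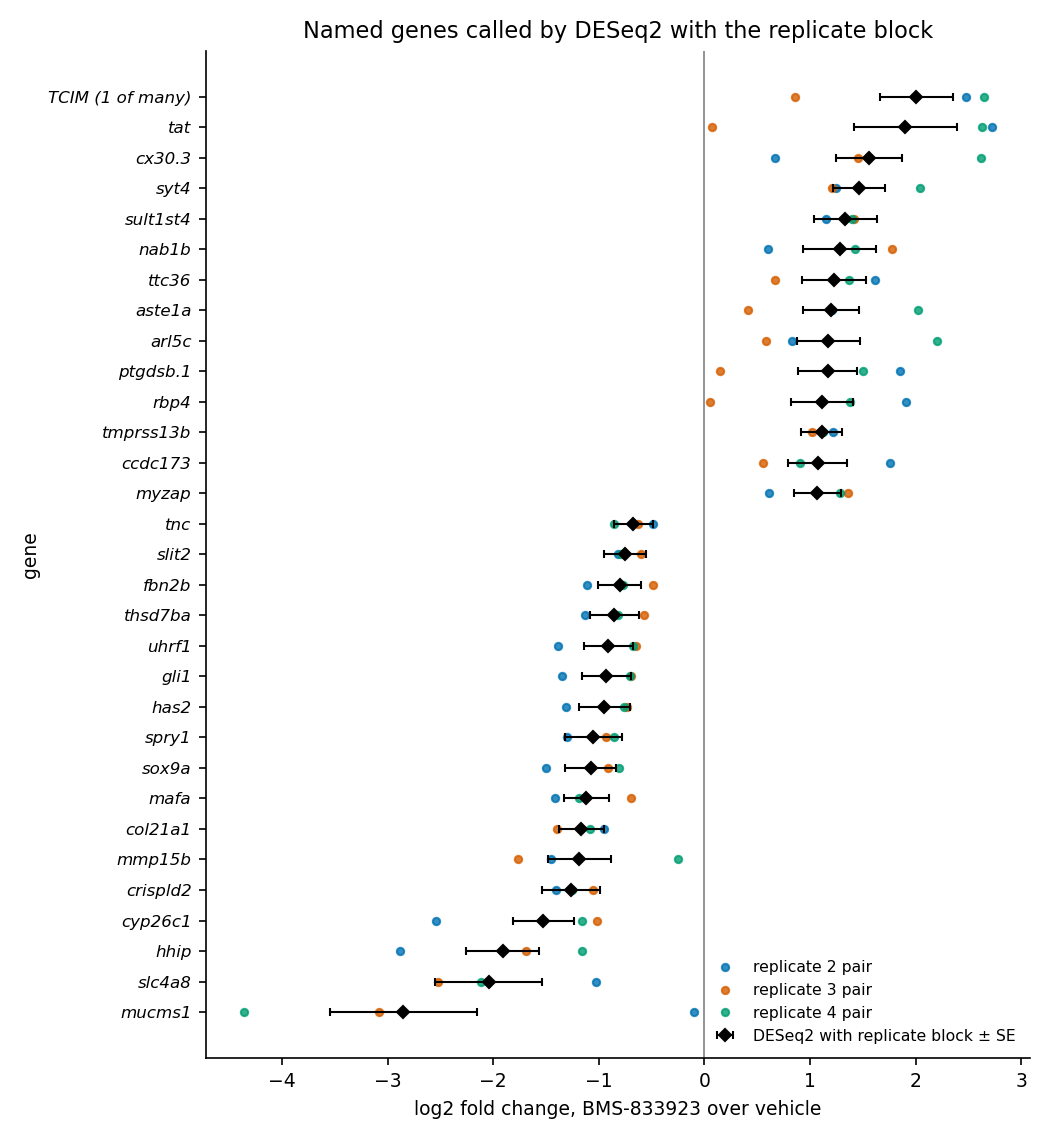
Log2 fold change of BMS-833923 over vehicle (horizontal axis) for genes named in the text and called by DESeq2 with the replicate block (vertical axis). Black diamonds are the fitted value ± SE and coloured points are the log2 fold within each same-number pair. All 3 pair values lie on the same side of 0 for each gene, and for tat, rbp4 and mucms1 1 pair lies close to 0.

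Of the 26 fixed lists, camera at the preset correlation called 3 higher and 8 lower without the block, and 4 higher and 10 lower with it. None was called with an estimated correlation or by fry, with or without the block. Camera called 3 lists without BMS replicate 4 and 7 without vehicle replicate 2. Of the 6 fits that leave out 1 library, 6 kept the call of the Hedgehog direct targets, 5 those of the Wnt, Notch and superficial epidermis lists, and 4 those of the xenobiotic and basal epidermis lists. The calls of the matrix remodelling, basement membrane and pathway component lists were kept in 3, and those of the Fgf and osteoblast lists in 2. A range given after a median is that of the fits with 1 library left out. For the lists below, examples were chosen after their values were seen, from the DESeq2 fit with the block, and did not pass over all genes unless stated. The Hedgehog direct targets had the lowest median (-1.12, range -1.4 to -0.94, camera adjusted p = 1e-16, and 0.22 with an estimated correlation). Wnt target genes had negative values in 15 of 17 members (median -0.31, range -0.44 to -0.15, adjusted p = 0.00044, and 0.61 with an estimated correlation). Among them were sp5a (-0.82 ± 0.42) and dkk1a (-0.71 ± 0.29), the latter a secreted Wnt inhibitor. The Notch list, which holds receptor and ligand genes beside target genes, was negative in 17 of 20 members (median -0.32, range -0.48 to -0.17, adjusted p = 0.0037, and 0.43 with an estimated correlation), with hey1 at -0.53 ± 0.29. Fgf target genes were negative in 12 of 16 (median -0.27, range -0.38 to -0.04, adjusted p = 0.042, and 0.66 with an estimated correlation). Among them spry1 passed over all genes with the block, and dusp5 went the other way (1.61 ± 0.73).

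The matrix remodelling list was negative in 23 of 33 members (median -0.24, range -0.49 to -0.03, camera adjusted p = 0.011, and 0.66 with an estimated correlation). It includes mmp15b and has2, which DESeq2 with the block called lower. The basement membrane and epidermal adhesion list was negative in 29 of 42 members (median -0.12, range -0.41 to 0.14, adjusted p = 0.025, and 0.69 with an estimated correlation). Its laminin gene lama1 (-0.72 ± 0.21) passed adjusted over the list alone in the DESeq2 fit with the block. The sign of this list's median turned to 0.14 without BMS replicate 4 and 0.04 without vehicle replicate 3. Xenobiotic and oxidative stress genes were positive in 18 of 23 members (median 0.24, range 0.14 to 0.35, adjusted p = 0.011, and 0.61 with an estimated correlation), among them the peroxiredoxin gene prdx1 (0.53 ± 0.21) and the aryl hydrocarbon receptor target cyp1a (0.62 ± 0.39). Immediate early and heat shock genes (28 of 40 positive) were called higher with the block (adjusted p = 0.022, and 0.66 with an estimated correlation). Without it the call depended on the setting (0.11 with TMM and 0.045 with total-count scaling). The mean level of these genes was 5.04 log2 CPM in vehicle replicate 4, against 5.74 to 6.05 in the other libraries, and it fell in pair 3 (6.05 to 5.82). Without both libraries of number 4 camera's direction turned to lower in the fit with the block (adjusted p = 0.17). Proliferation genes (23 of 34 negative) were called lower with the block (adjusted p = 0.038, and 0.67 with an estimated correlation), and without it by total-count scaling (0.01) and not by TMM (0.081). The retinoic acid list was not called (adjusted p = 0.21), and its cyp26c1 and rbp4 moved in opposite directions. The lists of Bmp and Tgf-beta targets (adjusted p = 0.62), cell migration and actomyosin (0.21) and sterol synthesis (0.23) were not called either.

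The lists of cell type markers moved in both directions. Superficial and intermediate epidermis markers were positive in 24 of 24 members without the block and in 22 with it (median log2 fold change 0.31 without it, range 0.21 to 0.47, camera adjusted p = 0.00044, and 0.61 with an estimated correlation), with the keratin gene krt17 at 0.56 ± 0.23. Their mean level rose mostly in pair 2, from 6.83 to 7.42 log2 CPM. In pairs 3 and 4 it went from 6.86 to 6.91 and from 7.11 to 7.22. Basal epidermis markers were positive in 17 of 21 (median 0.25, range 0.04 to 0.33, adjusted p = 0.012, and 0.64 with an estimated correlation). Their mean went from 7.41 to 7.83 in pair 2, from 7.32 to 7.3 in pair 3 and from 7.11 to 7.27 in pair 4. Osteoblast markers were negative in 18 of 25 (median -0.19, range -0.27 to 0.02, adjusted p = 0.024, and 0.66 with an estimated correlation). The osteoblast transcription factor genes sp7 (-0.61 ± 0.25) and runx2b (-0.75 ± 0.30) and the collagen gene col1a1a (-0.48 ± 0.18) each had an adjusted p of 0.0517 over the list alone by DESeq2 with the block. Fin mesenchyme and blastema markers were called lower with the block (adjusted p = 0.049, and 0.65 with an estimated correlation), and without it by total-count scaling (0.024) and not by TMM (0.056). Endothelial (adjusted p = 0.60), immune (0.23), pigment (0.68), nerve (0.49), blood (0.056) and muscle (0.47) markers were not called by camera. With no filter, muscle markers were called higher (adjusted p = 0.043) and blood markers lower (0.042), the latter also without vehicle replicate 4 (median -0.98), at the preset correlation. With an estimated correlation, all libraries and the main filter, the adjusted p was 0.66 for both. The BMS replicate 2 library stood apart from the others on the first principal component. Ribosomal protein genes took 8.30% of its counts, against 3.76% to 6.27% in the other libraries, and its TMM factor was 0.78, against 0.95 to 1.12. Its mean superficial epidermis marker level (7.42 log2 CPM) was the highest of the 6, where the others lay between 6.83 and 7.22.

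**Figure D3:**
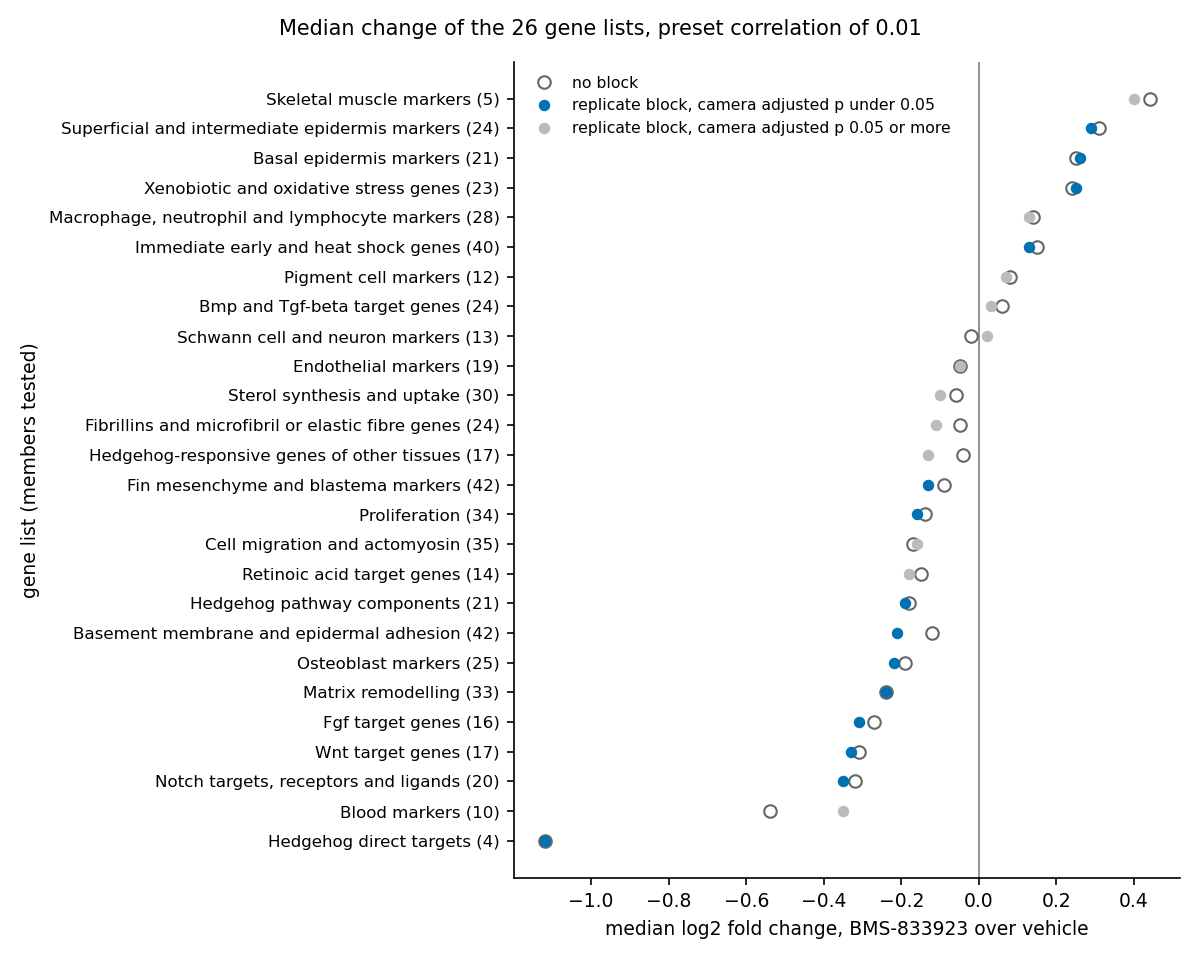
Median log2 fold change of BMS-833923 over vehicle (horizontal axis) for the 26 fixed gene lists, with the number of members tested in brackets (vertical axis). Open circles are fits without the block and filled circles fits with the replicate block, blue where camera at the preset correlation gave an adjusted p under 0.05. The Hedgehog direct targets lie at -1.12, and the other 25 lists lie between -0.54 and 0.44.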

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

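The fits named with a replicate block other than edgeR's quasi-likelihood test, the summed rows, the filter of the authors' table and the omission of both libraries of a number were chosen after seeing the data. For the count of genes changed without the block (0 by edgeR), DESeq2 and the edgeR likelihood ratio test gave 1, and all other planned settings gave 0, including the quasi-likelihood fit with the replicate block and the omission of each library. With the block, DESeq2 gave 72 and the likelihood ratio test 110, or 106, 100 and 76 with RLE, upper-quartile and total-count scaling. Total-count scaling moved the median of all genes to -0.134 in that fit. The quasi-likelihood fit with the block gave 9, 392 and 12 genes without both libraries of number 2, 3 and 4. With so few libraries left, the spread of each gene is drawn largely from other genes. These counts therefore do not show that a number hides changes. Against the 72 genes of DESeq2 with the replicate block, the quasi-likelihood test and limma-voom with the block gave 0, the likelihood ratio test 110 and DESeq2 without the block 1. Without both libraries of number 4 DESeq2 gave 5, of which 4 were among the 72, and it gave 99 without number 2 (36 shared) and 48 without number 3 (27 shared). All 72 kept their direction in these fits, but this was largely fixed beforehand. They were selected from the same libraries, and each had moved the same way in 3 of 3 pairs. Among the direct Hedgehog targets, 2 to 4 passed over the list alone when a library was left out, and 4 passed in all other settings. The count of called lists (11) was 0 with an estimated correlation and 0 with fry, with or without the replicate block, and 3 to 14 when a library was left out.

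Directions turned in some setting for 3 genes that passed no test and, by camera's direction, for 12 lists, of which 2 had been called and 10 had not. The log2 fold change of shha (0.10 without the block) was -0.052 with total counts, -0.071 with total-count scaling in the likelihood ratio test with the block, and -0.18 and -0.064 without both libraries of number 2 and of number 3. When a library was left out it ran from -0.065 to 0.34, that of gli2a from -0.39 to 0.11 and that of gli3 from -0.33 to 0.13. The median of the basement membrane list ran from -0.41 to 0.14 in the same way. Camera's direction for the Fgf target list turned without both libraries of number 3, where its median was -0.21 and its adjusted p 0.93. The 10 lists not called turned in settings where they were not called either. By camera's direction, the list of Hedgehog-responsive genes of other tissues turned with no filter (median 0.08), with CPM over 1 (-0.02) and without both libraries of number 3 (-0.15). Pigment markers turned with no filter (-0.16) and without number 4 (-0.09), nerve markers with CPM over 1 (-0.1), and immediate early genes without number 4 (-0.01). Blood (0.25), Bmp and Tgf-beta (-0.06), endothelial (-0.06) and muscle (0.09) lists turned without number 2. When a library was left out, medians ran from -0.21 to 0.11 for Hedgehog-responsive genes, -0.25 to 0.2 for pigment, -0.04 to 0.28 for immediate early genes and -0.98 to -0.12 for blood. They ran from -0.12 to 0.11 for Bmp and Tgf-beta, -0.18 to 0.17 for endothelial, -0.27 to 0.01 for proliferation and -0.21 to 0.14 for fibrillin lists. The cause was not tested in any of these cases. Camera takes the data and the design and not the test of single genes, so lists were run only under settings that change the former. With 3 libraries per group and large differences between numbers, the simulated 2-fold changes were found in 0% of cases without the block.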

Other observations

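Genes outside the naming rule that DESeq2 called with the replicate block were chosen here after their values were seen. Higher in BMS were the very-long-chain fatty acid elongase gene elovl1a (log2 fold change 1.06, adjusted p = 0.00017), the transglutaminase gene tgm5l (0.98, adjusted p = 0.00083), the desmosomal plakophilin gene pkp2 (1.04, adjusted p = 0.0302), the epithelial growth factor gene epgn (1.05, adjusted p = 0.022), the arginase gene arg2 (1.02, adjusted p = 0.00148) and the ornithine decarboxylase gene odc1 (0.79, adjusted p = 0.022). Lower in BMS was the fibrillar collagen gene col11a1b (-0.74, adjusted p = 0.0272).

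Tests whose result had been seen in part beforehand were those of shha, of the osteoblast share and of the splits by the other 2 edgeR tests with the block, and the glucocorticoid and clock lists were written after 6 of their members had been seen. The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05. The edgeR count was 0 for the real split and at most 0 for the others (10 of 10 splits as large). At an unadjusted p under 0.05 other splits gave up to 3412 genes against 198 in the real one, which points to a structure of the libraries other than the treatment. The 6 splits that part 1 pair and keep the other numbers together hold that value, while the 3 others that part each pair gave 80 to 125. Of the 4 splits that part each pair, the real one gave the most genes by DESeq2 with the replicate block (72, highest other 23, 1 of 4 as large). The likelihood ratio test with the block gave 110, and 26 at most in the others (1 of 4 as large). The quasi-likelihood test with the block gave 0 in the real split and 9 in the split of vehicle 2, vehicle 4 and BMS 3 against the rest (4 of 4 as large). That split also gave more genes at an unadjusted p under 0.05 (1399 against 1307). These 4 splits are too few for a share under 0.05. For the Hedgehog direct targets over the list alone, the real split gave 4 and the highest other 1 (1 of 10 as large). For lists called by camera, the real split gave 11 and the highest other 12 (2 of 10 as large), in a split that parts 1 pair. The 3 others that part each pair gave 4 to 6 lists and 0 of the targets.

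The fall of the 4 Hedgehog direct targets was weighed against differences in the dissected tissue. A smaller shha-expressing domain in the BMS pools would lower shha about as far as the targets, whose median was -1.12. Over the 3 pairs together, the lower bound of the log2 fold change of shha was -0.43 in the fit with the block. That bound uses a spread drawn in part from other genes. The folds of shha within pairs 2, 3 and 4 were 0.55, 0.20 and -0.61. In pair 4 those of gli1, ptch1 and hhip were -0.71, -0.84 and -1.16, so a smaller domain in that pair is not excluded. A smaller share of osteoblasts would lower their markers likewise, but the median of 25 markers was -0.22 with an SD of 0.31, which argues against this as the whole of the fall. A smaller fall in osteoblasts, or in 1 osteoblast stage, is not excluded and stays open. The BMS replicate 2 library alone does not account for it either, since the targets' median was -0.94 without both libraries of number 2, and 4 of 4 were lower within both other pairs. Inhibition of Smoothened stays open as the explanation that the design names.

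Among genes higher in BMS, fkbp5 and tat are known targets of the glucocorticoid receptor, and fkbp5 was singled out after its values were seen. In BMS fkbp5 was higher by 0.84, 1.91 and 4.08 log2 units within pairs 2, 3 and 4 and was called by the likelihood ratio test with the block (adjusted p = 0.0105) and not by DESeq2 (0.479). The folds of tat were 2.73, 0.07 and 2.63. Another gene of the glucocorticoid list seen beforehand, crispld2, was lower in 3 of 3 pairs (DESeq2 log2 fold change -1.26, adjusted p = 0.0041), while glula (0.85, adjusted p = 0.0583) and nfkbiab (0.85, adjusted p = 0.0148) were higher in 3 of 3. Of the clock genes not seen before, 0 of 23 tested passed 1 log2 unit in absolute value (in a fit with the block over the 3 pairs). This argues against a large difference in the time of day of collection that is shared by the pairs. However, the clock gene nr1d2a, which was seen before and is not among the 23, was at 1.04. With the block it was called by DESeq2 (adjusted p = 0.0308) and by the likelihood ratio test (0.0388). Within single pairs some of the 23 did pass, such as hlfa (1.43 in pair 3) and clocka (-1.15 in pair 2), examples chosen after their values were seen. Differences in time that vary between pairs are therefore not excluded. Limma's fry gave the clock list a mixed p of 0.233. A candidate explanation is higher glucocorticoid receptor activity in the BMS fish. The 22 responsive genes not seen before had a median of 0.40 (SD 0.51, 16 of 22 higher), but fry's directional p was 0.22, so it stays undecided.

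Libraries of the same number deviated together (r of 0.55 to 0.62). Different shares of connective tissue and epidermis in the dissected pools may contribute. Number 4 had the lowest mean osteoblast marker level (6.52 log2 CPM, against 6.94 and 6.97) and the highest superficial epidermis level (7.16, against 6.88 and 7.12). The ranges over the numbers were 0.46 for osteoblast and 0.28 for epidermis markers. Both lay under the 0.5 set beforehand as the least that would count, and by that rule they go against different shares. The epidermis range fell short by less than the error of such a difference (0.25), an allowance that was not part of the rule. This error comes from the spread between the vehicle and BMS libraries of a number, so it holds the treatment difference too. With that allowance the data do not decide. The labels give no day or clutch for the numbers, so these were not tested.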
